A study of Mus musculus with 9 samples.

How the data were processed

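Total RNA from the livers of 9 male C57bl/6J mice, 3 per diet group, was hybridised by the authors to 9 Agilent 1-colour (Cy3) mouse arrays. Per the labels, RNA integrity was checked and the RNA was cleaned on columns with a DNase step before labelling. The authors scanned the arrays with Feature Extraction (version 10.7 in the submitters' processing notes, 10.7.1.1 per the file headers). Per the file headers, the processed signal is an intensity per spot, background-subtracted and detrended within its array, with small values replaced by surrogates, and not normalised between arrays. The deposited table of all samples holds values that the authors put on the log2 scale. From the values, each array correlated at 0.9969 or more with the log2 processed signal, each column had a median of 4.98 or 4.99, and the distributions were nearly equal, as quantile normalization gives. Genes were not centred in that table, the submitters' notes name limma without its role, and the normalization step and limma version are not given in the sources used here. With 1 colour per array no ratio direction arises.

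The processed signals of the 9 arrays were read here with R 4.3.3 and data.table (1.17.8). Each array held 45018 spots, of which 1639 were controls. Spots that the scanner software marked as non-uniform or as population outliers were left out, replicate spots were averaged on the log2 scale to 41174 probes, and each array's 75th percentile was subtracted. A probe entered if its signal was well above background, by the scanner software's own call, on at least 3 of the 9 arrays, whatever their group (26478 probes), and each gene was represented by its brightest probe on average over all arrays. This left 17637 features, 5983 of them with more than 1 detected probe, and 5 values were missing. Probes were matched to RefSeq genes of the assembly GRCm38 for their names: 27668 probes by their own accession, 29 by another accession, 5589 by symbol and 460 by synonym, while 7428 of the 41174 probes had no match and kept the name in the file (3493 of the features tested). Probe positions are those in the file headers' mm9 annotation, with the chromosome, start and end; whether a probe lies in an exon or an intron was not determined, since no genome sequence was used here. Probes of near-identical paralogs (Cyp2b, Cyp3a, Hspa1 and Mup genes) can read each other's transcripts.

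The 3 groups were compared in limma 3.58.1 (lmFit and eBayes) with 1 fit over all 9 arrays, 6 residual degrees of freedom and 2.2 prior degrees of freedom, for HFD against chow, HFD+APS against HFD and HFD+APS against chow. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all features, from limma's 2-sided moderated test. Changes are log2 differences ± SE, group values are means ± SD of 3 arrays, and "at least N-fold" marks a gene whose signal in the lower group was not well above background on any array, with values of that group raised to at least the lowest signal called well above background on their array and the adjusted p taken from the fit. No fold is given where this left no bound. The 3 comparisons share their groups, so their results are not independent. With 3 arrays per group, 10% of features have non-overlapping groups by chance.

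The comparisons, 30 gene lists (19 of pathways and responses and 11 of cell type markers), the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists had 590 entries for 573 distinct genes, of which 17 stood in more than 1 list, 511 were tested and 62 were not analysed here. Genes among the latter include Pck1, Irs2, Mup20, Ly6g and Prss1. Many markers of the cell type lists are also expressed by hepatocytes or by other cells of the liver. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 30 lists in each comparison, and again with an estimated correlation. With the preset correlation 11, 14 and 7 lists were called in the 3 comparisons, and with the estimated correlation 0 were called in each (smallest adjusted p = 0.459, 0.33 and 0.934; 2, 4 and 1 at an unadjusted p under 0.05). The genes named were, for each comparison, the 8 largest rises and 8 largest falls among features past the threshold with non-overlapping groups and no clone-like name, up to 4 members of each list with the smallest p, and 14 genes fixed in advance (Scd1, Fasn, Srebf1, Cd36, Pparg, Cidea, Cidec, Cyp7a1, Fgf21, Cyp4a14, Sqle, Ccl2, Col1a1 and 1 more). Some called or fixed genes, and counts of called genes that rest on them, are not reported here. For the overlap of the comparisons, the 8 genes with the largest product of opposite changes were added. Other genes are marked as named after their values were seen.

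The slide of each array follows from the array barcodes in the file names. HFD+APS was also compared with HFD within the slide that holds HFD+APS 1 and the HFD arrays, with slide as a fixed block, whose estimate is the same difference by construction, and with slide as a random block (duplicateCorrelation, with statmod 1.5.0). The comparisons against chow allow the random block but no within-slide value. The share of HFD changes with the opposite sign in HFD+APS was set against 100 simulations with the same shared arrays. Their first version took the measured HFD changes as true and called too many features. These changes were then shrunk on a scale of 2 standard errors, chosen after seeing the data. The shrunk version called 1270 features in HFD against chow (1190 to 1370) against 1929 observed, so its values come from weaker changes than the measured ones. The other alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the authors' table, no filter on dim probes, probes well above background on all 9 arrays, the mean over a gene's probes, a fold change of at least 2, a block for replicate number, array weights, an intensity trend with a robust prior, each array left out in turn, and only the groups compared. The restriction to features matched to RefSeq genes and a common floor were added after seeing the data.

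The procedure was tested on simulated data of 17632 features with 200 changed. In the 3 comparisons it recovered 60, 63 and 67% of 2-fold changes and 91, 92 and 92% of 4-fold changes. Of unchanged features 8, 8 and 7 were called (5, 4.9 and 4.2% of calls). A list shifted by 1.5 SD was called in each comparison and 0 of the 29 others were. This cannot test list calls with correlated genes. Signal over background and the number of arrays, 3 per group, limit the precision. Replicate spots of an array and probes of a gene are not independent samples.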

Results

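Liver gene expression was measured in male C57bl/6J mice at 16 weeks of age, after 12 weeks on 1 of 3 diets. The chow group ate standard food, and the HFD group ate a high-fat diet with fat at 60 kcal%. The HFD+APS group ate the same high-fat diet with Astragalus polysaccharides (APS), carbohydrates prepared from a plant used in Chinese medicine, at 40 g per kg of diet. Each group held 3 livers, with 1 array per liver, and these livers had been picked from a study of 24 mice by their HE staining and TG results. The p-values therefore measure the spread between these selected livers, and the number of arrays limits the precision.

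Every array carried 45018 spots, 1639 of them controls, and the upper-quartile signal to which each array was scaled lay between 214.4 (chow 2) and 272.8 (HFD 2). The 3 chow arrays shared 1 slide, the 3 HFD arrays and HFD+APS 1 shared another, and HFD+APS 2 and HFD+APS 3 lay on the third. The share of spots well above background was 61.5 to 68.4% on the chow slide, 50.4 to 54.1% on the slide with the HFD arrays and 63.5 to 64.5% on the last slide. Negative control spots read 41.6 to 42.4, 55.0 to 61.6 and 37 to 40.4 on the same slides. Correlations across the tested features, which are not independent replicates, were 0.9791 to 0.9924 within groups and 0.9633 to 0.9843 between groups. The first principal component held 31.3% of the variance and placed HFD+APS (0.5 to 3.4) between chow (-46 to -30.4) and HFD (27.3 to 50.9). The second component held 21.4% and set HFD+APS 2 and HFD+APS 3 (-49.6 and -39.7) apart from HFD+APS 1 (0.2).

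The comparison of HFD with chow asked which liver transcripts differed after fat feeding. Past the threshold, 12 of 19 cell cycle genes, 5 of 21 fat storage genes and 3 cytochrome P450 genes of the Cyp2b family rose, and 5 of 16 male-biased genes fell. No list was called with an estimated correlation (smallest adjusted p = 0.459). Cidea, which codes for a lipid droplet protein scarce in lean liver, rose 152-fold, from -2.85 ± 0.23 in chow to 4.40 ± 1.58 in HFD (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3 per group). Cyp2b9, a P450 enzyme with higher expression in female than in male liver, rose 22.8-fold, from 1.66 ± 0.17 to 6.18 ± 0.51. Cdc20, an activator of the anaphase-promoting complex, rose 9.02-fold, and Lgals1, a galectin, rose 7.96-fold, from 2.15 ± 0.21 to 5.14 ± 0.25.

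Among 21 measured genes of lipid droplets and fat storage, 5 rose and 0 fell (7 and 0 adjusted over the list alone). The median log2 change was 0.55, with a camera adjusted p = 0.000406 (adjusted p = 0.459 with an estimated correlation). The log2 change of Cidea was 7.25 ± 0.65 (SE; limma adjusted p = 0.0019), with its probe on chromosome 18 from 67527351 to 67527410 (mm9). Mogat1, which makes diacylglycerol in an alternative route to triglyceride, rose by 2.70 ± 0.13 (adjusted p = 0.000354; chromosome 1, 78534646 to 78534705), and its probes ranged from 2.70 to 3.74. Cd36, a fatty acid uptake receptor, rose by 2.07 ± 0.19 (adjusted p = 0.00204). Fitm1, which partitions fat into droplets, rose by 1.22 ± 0.20 and lost its call without chow 2 (adjusted p = 0.0512). Plin3, a droplet coat protein named after its value was seen, rose by 0.56 ± 0.14 and lost its call without chow 1, chow 2, chow 3, HFD 1, HFD 3 or HFD+APS 3 (adjusted p up to 0.107). Cidec (1.80 ± 0.73, adjusted p = 0.138) and Pparg (0.59 ± 0.28, adjusted p = 0.181), the adipogenic nuclear receptor, did not pass. The adipocyte list (4 measured, 1 rose and 0 fell, 3 and 0 adjusted over the list alone) had a median of 2.85 (adjusted p = 0.0105; adjusted p = 0.459 with an estimated correlation; 0.43 and 0.177 without a filter on dim probes). Its only called gene was Cidea, while Cfd, which codes for adipsin, stood at 4.44 ± 1.44 (adjusted p = 0.0812).

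Lipoprotein genes included Apoa4, an apolipoprotein of triglyceride-rich particles, which rose 11.5-fold (3.52 ± 0.49, adjusted p = 0.00944), and Apoc2, the cofactor of lipoprotein lipase, which rose 1.77-fold (0.83 ± 0.10, adjusted p = 0.0052). Pltp, the phospholipid transfer protein, rose by 1.12 ± 0.28, a call lost without any 1 of the chow or HFD arrays or HFD+APS 3 (adjusted p up to 0.127). Across 19 lipoprotein genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), the median was -0.09, the mean 0.18 and the test pointed up (adjusted p = 0.81). Among 20 lipogenesis genes 2 rose and 1 fell (3 and 2 adjusted over the list alone), with 14 positive changes and a median of 0.16 (adjusted p = 0.177). The risers were Thrsp, a lipogenic regulator (3.07 ± 0.75, adjusted p = 0.0389), and Fads2, a fatty acid desaturase (0.95 ± 0.20, adjusted p = 0.0283), and Gpam, the first enzyme of glycerolipid synthesis, fell by 0.53 ± 0.12. Thrsp lost its call without any chow array, HFD 1, HFD 2, HFD+APS 2 or HFD+APS 3 (adjusted p up to 0.123). Fads2 lost its call without any chow array, HFD 1 or HFD 2 (up to 0.0804) and Gpam without any chow array, HFD 2, HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.0994). Scd1 (1.19 ± 0.59, adjusted p = 0.208), Fasn (-0.16 ± 0.34, adjusted p = 0.781) and Srebf1 (0.16 ± 0.40, adjusted p = 0.819) did not pass. The lipogenesis list was called without HFD 3 (0.23, adjusted p = 0.0347). Of 23 cholesterol genes, Hsd17b7, an enzyme of the late sterol pathway, fell by 0.95 ± 0.14 (adjusted p = 0.0118) and 0 rose (0 and 1 adjusted over the list alone). Sqle (-0.57 ± 0.79) did not pass, and the cholesterol list had a median of -0.16 (adjusted p = 0.566; -0.43 and 0.011 without chow 2).

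Among 34 genes of fatty acid oxidation 3 rose and 3 fell by either adjustment (over all genes or adjusted over the list alone) and 28 did not pass, with 12 positive and 22 negative changes and a median of -0.09 (adjusted p = 1). Higher were Vnn1, a pantetheinase and PPAR alpha target (1.07 ± 0.19, adjusted p = 0.0178), Ucp2, a mitochondrial carrier (1.43 ± 0.32, adjusted p = 0.0313), and Hadh (0.58 ± 0.14, adjusted p = 0.0376). Lower were Angptl4, an inhibitor of lipoprotein lipase (-0.78 ± 0.15, adjusted p = 0.0216), Acot1, a thioesterase (-1.18 ± 0.27, adjusted p = 0.0333), and Ehhadh (-1.52 ± 0.40, adjusted p = 0.0472). Hadh and Ehhadh were named after their values were seen. Without chow 3 each of these 6 calls was lost (adjusted p up to 0.0588 for Vnn1, 0.0936 for Ucp2, 0.101 for Hadh, 0.075 for Angptl4, 0.107 for Acot1 and 0.142 for Ehhadh over the arrays left out). Chow 2 and HFD 2 or HFD 3 also ended calls among them, as did chow 1, HFD 1 and HFD+APS 3 for Ucp2, Acot1, Hadh and Ehhadh. Cyp4a14 (-0.71 ± 0.26, adjusted p = 0.114) and Fgf21, a liver hormone of fasting (-0.96 ± 0.53, adjusted p = 0.25), did not pass.

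All livers came from males. In the female-biased list (16 measured) 6 rose and 3 fell (6 and 4 adjusted over the list alone), with a median of 0.07 (adjusted p = 0.21). Cyp2b9 rose by 4.51 ± 0.26 (adjusted p = 0.000457; chromosome 7, 26995607 to 26995666), Cyp2b13 by 4.40 ± 0.32 (adjusted p = 0.00117) and the sulfotransferase gene Sult3a1 by 2.08 ± 0.17 (adjusted p = 0.00157). Cyp2b10, a target of the receptor CAR, rose by 3.21 ± 0.49 and lost its call without chow 2 (adjusted p = 0.0505). The Cyp2b probes can cross-hybridise between these near-identical genes, so their separate values are uncertain, and the same holds for Cyp3a genes. The other called members were named after their values were seen. Hao2, a peroxisomal oxidase, was at least 4.06-fold higher, a bound because its signal was not well above background in chow (adjusted p = 0.024), and Abcd2 rose by 1.18 ± 0.29. Cyp3a16 (-2.20 ± 0.36), Cyp3a44 (-2.23 ± 0.38) and Cyp3a41a (-1.87 ± 0.32) fell. Leaving out chow 2 ended each of those 5 calls, which reached adjusted p = 0.0717, 0.105, 0.0545, 0.0619 and 0.0632 when 1 array was left out. Chow 3 also ended 4 of them, all but Cyp3a16, and chow 1, HFD 1 or HFD 2 ended those of Hao2 and Abcd2, as HFD+APS 3 did for Abcd2. In the male-biased list (16 measured) 5 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of -0.76 (adjusted p = 0.000406; adjusted p = 0.459 with an estimated correlation). Gstp1, a glutathione transferase, fell by 1.14 ± 0.15 (adjusted p = 0.0073). Susd4, a complement regulator, fell by 1.04 ± 0.18 and lost its call without chow 2 (adjusted p = 0.06). Elovl3, a fatty acid elongase, fell by 2.01 ± 0.35 and lost it without chow 2 or chow 3 (adjusted p up to 0.0632). Cyp7b1, an oxysterol hydroxylase (-0.90 ± 0.22), and C6, a complement protein named after its value was seen (-0.89 ± 0.23), lost their calls without any chow array, HFD 1, HFD 2 or HFD+APS 3 (adjusted p up to 0.101 and 0.114). Cyp7b1 also lost it without HFD 3 and C6 without HFD+APS 2.

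Of 31 P450 and conjugation genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone), with a median of -0.16, a mean of 0.01 and a test pointing down (adjusted p = 0.645). The risers were the Cyp2b genes. Beside Gstp1 and Cyp3a16, Cyp3a11, the main drug-metabolising P450 of mouse liver (-2.03 ± 0.41, adjusted p = 0.0238), and Ces2a, a carboxylesterase (-1.60 ± 0.37, adjusted p = 0.0353), fell, named after their values were seen. Cyp3a11 lost its call without chow 2 or chow 3 (adjusted p up to 0.0814) and Ces2a without any chow array, HFD 2, HFD 3 or HFD+APS 3 (up to 0.103). In HFD 3 this list had a score of -0.79 against 0.04 and 0.26 in HFD 1 and HFD 2, where a score is the median of a list's genes after each gene was centred over the 9 arrays.

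Of 19 measured cell cycle genes 12 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 1.07 (adjusted p = 2.39e-08; adjusted p = 0.459 with an estimated correlation). Cdc20 rose by 3.17 ± 0.33 (adjusted p = 0.00367; chromosome 4, 118105536 to 118105595) and Ccnb2, a mitotic cyclin, by 2.04 ± 0.21 (adjusted p = 0.00375; chromosome 9, 70255671 to 70255730). Mki67, the proliferation marker, rose by 2.14 ± 0.27 (adjusted p = 0.00687) and Ccna2, the cyclin of S phase and G2, by 2.48 ± 0.34 (adjusted p = 0.00944). These 4 calls held in all 9 fits that left out 1 array. The cell cycle score was 0.60 to 1.14 in the 3 HFD arrays and at most -0.08 in the other 6.

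Of the immune and stromal lists 7 were called higher in HFD and lost these calls with an estimated correlation (adjusted p from 0.557 to 0.83). HFD 3 stood apart in several of these lists: its scores were 2.83 for neutrophil markers, 1.28 for acute phase proteins, 1.14 for inflammatory cytokines and receptors, 1.09 for monocyte-derived macrophages and 0.51 for lymphocyte markers. Of 25 interferon response genes 9 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.93 (adjusted p = 3.26e-09; adjusted p = 0.557 with an estimated correlation). Psmb9, an immunoproteasome subunit, rose by 1.31 ± 0.17 (adjusted p = 0.0073), and Ifit3, an interferon-induced protein, rose by 1.04 ± 0.16 and lost its call without chow 2 (adjusted p = 0.0507). In the inflammatory list (19 measured) 0 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.50 (adjusted p = 0.0376; adjusted p = 0.83 with an estimated correlation). The genes that fell were Nfkbia, an inhibitor of NF-kB (-0.59 ± 0.13, adjusted p = 0.0302), and Socs3, an inhibitor of cytokine signalling (-0.57 ± 0.15, adjusted p = 0.0477). The probes of Socs3 ranged from -0.57 to 1.17 and their mean was 0.30 (adjusted p = 0.727). Nfkbia lost its call without any chow array, HFD 2, HFD 3 or HFD+APS 3 (adjusted p up to 0.0965) and Socs3 without any array but HFD+APS 1 (up to 0.133). Ccl2, a monocyte chemokine, stood at 1.87 ± 0.55 (adjusted p = 0.0628). The inflammatory list lost its call without chow 2 (0.36, adjusted p = 0.114) or HFD 3 (0.23, adjusted p = 0.305), with slide as a random block (0.46, 0.0778), with array weights (0.27, 0.181), without a filter on dim probes (0.40, 0.176) and with probes well above background on all 9 arrays (0.53, 0.116). The acute phase list (25 measured, 1 rose and 0 fell, 1 and 0 adjusted over the list alone) had a median of 0.71 (adjusted p = 0.00749; adjusted p = 0.83 with an estimated correlation). It lost its call without chow 1 (0.46, adjusted p = 0.0559) or HFD 3 (0.18, adjusted p = 0.24). Its called gene Steap4, a metalloreductase, rose by 1.92 ± 0.42, a call lost without any 1 chow array (adjusted p up to 0.0874).

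Of 15 Kupffer cell and macrophage markers 0 passed over all genes (8 and 0 adjusted over the list alone), with a median of 1.05 (adjusted p = 0.000246; adjusted p = 0.709 with an estimated correlation). Chow 2 stood apart, with Kupffer scores of -1.32 against -0.36 and -0.02 in chow 1 and chow 3, and was also the lowest array for stellate (-0.79), endothelial (-0.54) and red blood cell markers (-1.16). Without it the Kupffer median was 0.64 (adjusted p = 0.00139). Clec4f, a Kupffer cell lectin, stood at 1.03 ± 0.28 (adjusted p = 0.0505). The 11 monocyte-derived macrophage markers had 2 higher and 0 lower (5 and 1 adjusted over the list alone), with a median of 1.04 (adjusted p = 0.000749; adjusted p = 0.709 with an estimated correlation). Ly6c2, a monocyte surface protein, rose 3.71-fold (1.89 ± 0.26, adjusted p = 0.00944), and Trem2, a receptor of lipid-associated macrophages, rose by 2.33 ± 0.50, a call lost without chow 2, chow 3 or HFD 3 (adjusted p up to 0.0948). Of 18 stellate cell and fibrosis markers 2 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.48 (adjusted p = 8.89e-05; adjusted p = 0.709 with an estimated correlation). Col3a1 rose by 1.79 ± 0.30 with probes from -0.22 to 1.79 and lost its call without chow 2 (adjusted p = 0.0505). Col1a1 rose by 2.08 ± 0.45, a call lost without chow 2, chow 3, HFD 1 or HFD 3 (up to 0.0987). Endothelial markers (13 measured) had 2 higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.000749; adjusted p = 0.709 with an estimated correlation). Those were Clec4g (0.80 ± 0.20, adjusted p = 0.0394, with probes from -0.03 to 0.80) and Oit3 (0.92 ± 0.24, adjusted p = 0.0461). Clec4g lost its call without any array but HFD+APS 1 (adjusted p up to 0.106), and Oit3 without chow 1, chow 3, any HFD array, HFD+APS 2 or HFD+APS 3 (up to 0.111). The 5 neutrophil markers (0 and 0, 1 and 0 adjusted over the list alone) had a median of 1.22 (adjusted p = 0.0835) and were called without chow 3 (adjusted p = 0.04), HFD 1 (0.0344) or HFD 2 (0.026). In the lymphocyte list (17 measured; 0 and 0 adjusted over the list alone) the called gene was Cd4, at least 1.39-fold lower (adjusted p = 0.0404), and the median was -0.24 (adjusted p = 0.374; -0.51 and 0.0121 without HFD 3). Cd4 lost its call without any chow or HFD array or HFD+APS 2 (adjusted p up to 0.124).

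**Figure D1:**
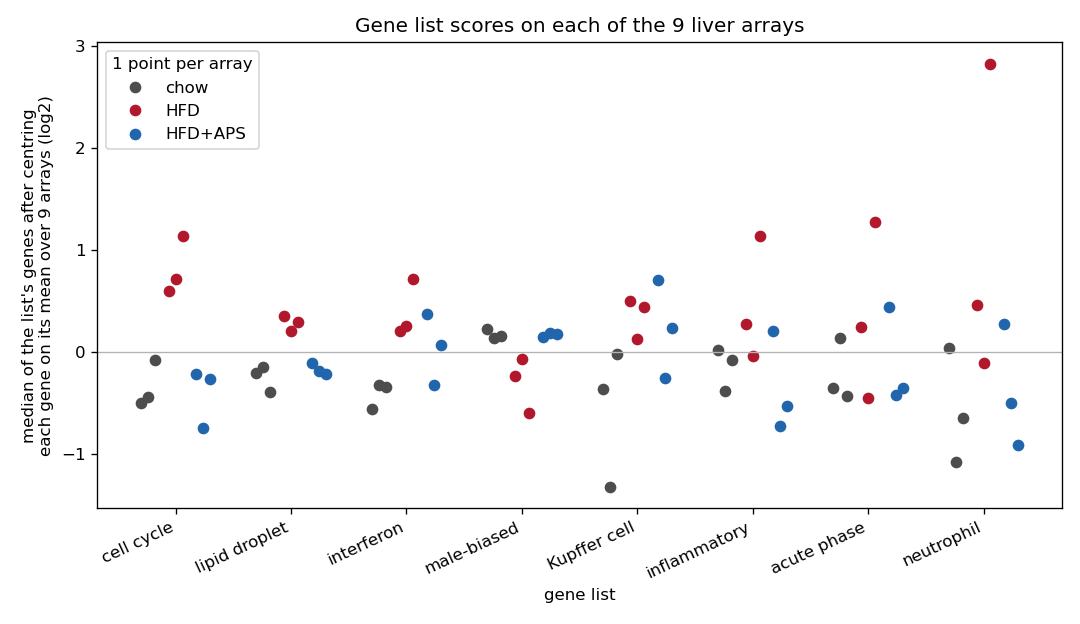
Each point is the score of 1 list in 1 liver, the median over the list's genes of the log2 signal after each gene was centred on its mean over the 9 arrays. The cell cycle scores of the 3 HFD livers (0.60, 0.72 and 1.14) lie above those of the 6 other livers.

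Among the other lists, 18 genes of glucose metabolism had 1 higher and 3 lower (2 and 3 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.81). Irs1, the insulin receptor substrate, fell by 0.93 ± 0.17 (adjusted p = 0.0178), and lost its call without chow 2 or HFD 3 (up to 0.066). Pcx, pyruvate carboxylase, rose by 0.50 ± 0.11, and Tat, tyrosine aminotransferase (-0.73 ± 0.18), and Igfbp2, an IGF-binding protein (-2.15 ± 0.55), fell. These 3 lost their calls without any chow array, HFD 1 or HFD+APS 3 (adjusted p up to 0.0842, 0.115 and 0.138), Pcx and Tat also without HFD 2, Tat and Igfbp2 also without HFD 3 or HFD+APS 2. The immediate early and heat shock list (18 measured, 0 higher and 3 lower, 0 and 3 adjusted over the list alone) had a median of -0.27 (adjusted p = 0.177; -0.43 and 0.00299 without HFD 3). Gadd45b, a stress-induced gene, fell by 1.79 ± 0.34, a call lost without chow 1, chow 2 or any HFD array (adjusted p up to 0.07). The paralogs Hspa1a (-1.41 ± 0.34) and Hspa1b (-1.32 ± 0.34), inducible heat shock proteins, lost theirs without any chow array, HFD 1, HFD 2, HFD+APS 2 or HFD+APS 3 (up to 0.12 and 0.137). Unfolded protein response genes (21 measured, 0 past and 0 adjusted over the list alone) had a median of 0.31 (adjusted p = 0.0566). They were called without chow 2 (0.45, adjusted p = 0.00365), chow 3 (0.20, 0.046), HFD 1 (0.35, 0.0101) or HFD 2 (0.31, 0.0175). The clock list (17 measured) had a median of 0.21 (adjusted p = 0.288). The list medians and adjusted p were 0.04 and 0.554 for NRF2 antioxidant genes, -0.02 and 1 for oxidative phosphorylation, -0.14 and 0.515 for hepatocyte markers and -0.39 and 0.324 for exocrine pancreas. Without HFD 3 the oxidative phosphorylation list was called in the other direction (0.10, adjusted p = 0.0339). For cholangiocyte markers the median was -0.07 and the mean -0.08 while the test pointed up (adjusted p = 0.997), and for red blood cell markers the median was -0.10, the mean 0.03 and the test up (adjusted p = 0.951). In these 6 lists 0 genes passed, adjusted over all genes or adjusted over the list alone. Bile acid genes (26 measured) had 0 higher and 1 lower, Cyp7b1 (0 and 0 adjusted over the list alone), and a median of -0.17 (adjusted p = 0.81). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -0.14 ± 0.54 (adjusted p = 0.89).

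The largest rises beyond these lists were in Adgrv1, an adhesion receptor (15.1-fold, 3.92 ± 0.41, adjusted p = 0.00371), Lockd, a noncoding RNA next to Cdkn1b (at least 11.9-fold, adjusted p = 0.0019), and Fam183b (at least 4.93-fold, adjusted p = 0.00529). Lgals1 rose by 2.99 ± 0.20 (adjusted p = 0.000821; chromosome 15, 78760566 to 78760625). Meg3, an imprinted noncoding RNA, fell 12.1-fold, from 1.16 ± 0.40 to -2.44 ± 0.71 (adjusted p = 0.00517; chromosome 12, 110809678 to 110809737). The other large falls ended not well above background in HFD: Srgap3 fell at least 4.12-fold, Adgrf1 at least 3.31-fold, Btbd35f1 at least 2.11-fold, Crhr2 at least 1.69-fold and Gpr85 at least 1.46-fold (adjusted p from 0.000821 to 0.0106). An immunoglobulin kappa variable gene (chromosome 6, 68170470 to 68170529) fell at least 1.6-fold (adjusted p = 0.00529). Tubb2b, a beta-tubulin, fell by 2.47 ± 0.63, a call lost without any chow array, HFD 2, HFD 3, HFD+APS 2 or HFD+APS 3 (adjusted p up to 0.12).

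Over all 17637 features, 803 were higher and 1126 lower in HFD (10.9% past the threshold; 5544 at an unadjusted p under 0.05), and 259 and 409 of these moved at least 2-fold. Falls were concentrated in dim features: the dimmest of 5 brightness classes held 68 higher and 319 lower (median log2 -0.193), the brightest 166 and 120 (0.019), and features not matched to a RefSeq gene held 44 and 420. The excess of falls depended on the processing: 821 were higher and 773 lower among matched features only, 759 and 735 after normexp background correction, and 939 and 955 with probes well above background on all 9 arrays. The count was 365 without chow 2, 548 without chow 3, 726 without HFD 3, 749 without HFD 2, 963 without chow 1, 1133 without HFD+APS 3 and 1144 without HFD 1. Of the 61 called genes named by rule, 27 kept their call in all 9 of these fits. With slide as a random block 684 features passed and 39 of the 61 genes kept their call, but all chow arrays shared a slide that held no other group, so chow and its slide cannot be told apart.

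**Figure D2:**
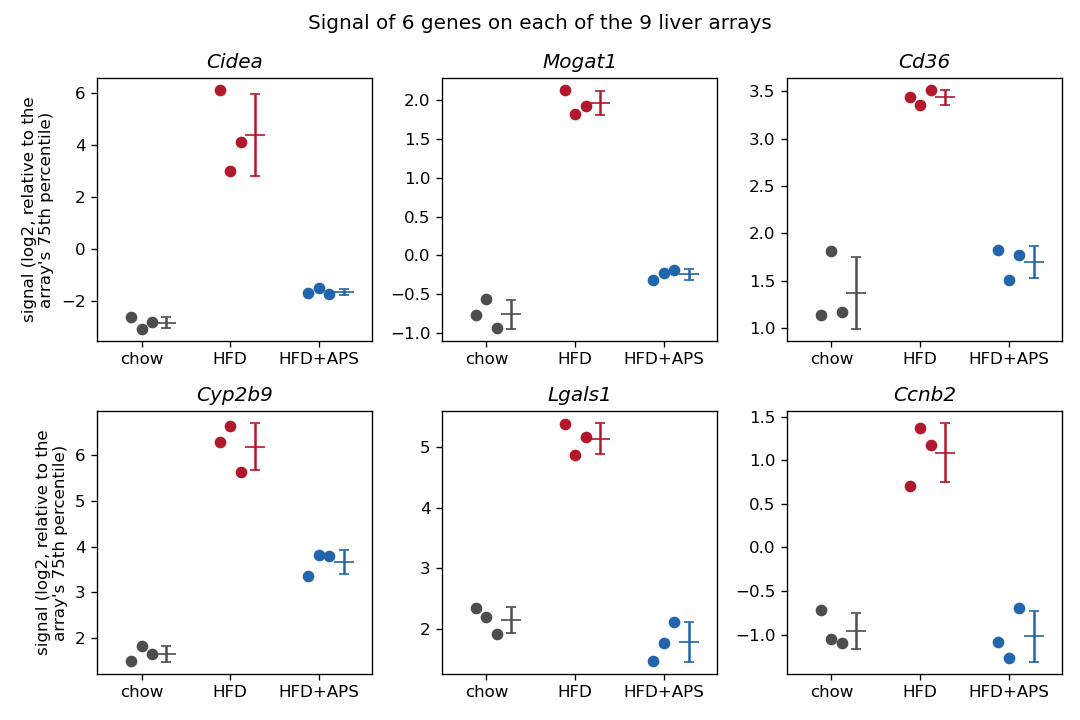
Each point is the log2 signal of a gene in 1 liver, relative to the array's 75th percentile, and each bar gives the group mean ± SD (n = 3). Cidea lay between 2.98 and 6.10 in the HFD livers and between -1.74 and -1.53 in the HFD+APS livers, and Cyp2b9 had means of 1.66, 6.18 and 3.66 in chow, HFD and HFD+APS.

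The comparison of HFD+APS with HFD asked which transcripts differed when the fat diet contained APS. Past the threshold, 9 of 19 cell cycle genes, 4 of 21 fat storage genes, Cyp2b9 and Cyp2b13 fell and 2 of 16 male-biased genes rose. No list was called with an estimated correlation (smallest adjusted p = 0.33). Cidea fell 66.9-fold, from 4.40 ± 1.58 in HFD to -1.67 ± 0.12 in HFD+APS, and Mogat1 fell 4.59-fold, from 1.95 ± 0.15 to -0.25 ± 0.07 (log2 signal, mean ± SD, n = 3 per group). Ccnb2 fell 4.29-fold, from 1.09 ± 0.34 to -1.02 ± 0.29, and Lgals1 fell 10.2-fold, from 5.14 ± 0.25 to 1.79 ± 0.33. Because HFD+APS 1 shared its slide with the 3 HFD arrays and the other HFD+APS arrays did not, many changes are also given within that slide. This value is HFD+APS 1 minus the mean of the HFD arrays, with the lone array assumed to vary like the groups.

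In the list of lipid droplets and fat storage (21 measured) 0 rose and 4 fell (0 and 5 adjusted over the list alone). Its median was -0.27 (camera adjusted p = 7.96e-05, and 0.33 with an estimated correlation), and -0.59 within the slide. Mogat1 fell by 2.20 ± 0.13 (adjusted p = 0.000609; -2.27 within the slide, adjusted p = 0.00665, and 0.0457 with the fixed block). Cidea fell by 6.06 ± 0.65 (adjusted p = 0.01; -6.12 within the slide, 0.0405) and Cd36 by 1.74 ± 0.19 (adjusted p = 0.01; -1.62 within the slide, 0.0488). Plin4, a droplet coat protein, fell by 2.36 ± 0.33 (adjusted p = 0.0214; -2.22 within the slide, 0.0962), a call lost without HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.0748). Cidec (-2.37 ± 0.73, adjusted p = 0.154) and Pparg (-0.78 ± 0.28, adjusted p = 0.194) did not pass. The adipocyte list (4 measured, 0 higher and 1 lower, 0 and 3 adjusted over the list alone) had a median of -3.11, and -3.21 within the slide. Over all arrays its camera adjusted p was 0.0163, and 0.33 with an estimated correlation. It lost its call without HFD 3 (-2.81, 0.066), HFD+APS 1 (-3.06, 0.0646) or a filter on dim probes (-0.76, 0.0599).

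Of 20 lipogenesis genes 0 passed over all genes (0 and 2 adjusted over the list alone), and 19 of 20 log2 changes were negative. The median was -0.31 (adjusted p = 0.00037, and 0.53 with an estimated correlation), and -0.56 within the slide. The score was -0.47 in HFD+APS 1 and 0.03 and -0.15 in the other HFD+APS arrays. Acacb, which makes the malonyl-CoA that limits fatty acid entry into mitochondria, stood at -0.89 ± 0.19 (adjusted p = 0.0628) and Acly, ATP citrate lyase, at -0.44 ± 0.10 (adjusted p = 0.085). Scd1 (-1.56 ± 0.59, adjusted p = 0.221), Fasn (-0.50 ± 0.34, adjusted p = 0.468), Srebf1 (-0.10, adjusted p = 0.921) and Thrsp (-2.34 ± 0.75, adjusted p = 0.162) did not pass. The cholesterol list (23 measured, 0 past and 0 adjusted over the list alone) had a median of -0.09 (adjusted p = 0.442). The median was -0.78 within the slide, which rests on HFD+APS 1 alone, and -0.38 without HFD+APS 2 (adjusted p = 0.0254). Its score was -0.68 in HFD+APS 1 and 0.19 and 0.04 in HFD+APS 2 and HFD+APS 3, with Sqle at -0.45 (adjusted p = 0.806). For 34 fatty acid oxidation genes (0 past and 0 adjusted over the list alone) the median was 0.00, the mean -0.09 and the test pointed down (adjusted p = 0.442; within the slide -0.01 and 0.573). Without HFD 3 the list was called (-0.08, adjusted p = 0.0382). Fgf21 (-0.09, adjusted p = 0.952) and Cyp4a14 (0.33, adjusted p = 0.548) did not pass. Lipoprotein genes (19 measured, 0 past, 3 and 2 adjusted over the list alone) had a median of -0.01 and a mean of -0.05 while the test pointed up (adjusted p = 0.794; 0.10 within the slide). Apoa4 stood at -2.49 ± 0.49 (adjusted p = 0.0531).

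Bile acid genes (26 measured) had 1 higher and 0 lower (2 and 0 adjusted over the list alone). Their median was 0.35 (adjusted p = 0.000317; adjusted p = 0.33 with an estimated correlation) and 0.13 within the slide (adjusted p = 0.083, and 0.0707 with the fixed block). Cyp7b1 rose by 1.40 ± 0.22 (adjusted p = 0.0305; 1.51 within the slide, 0.0919), a call lost without chow 2, chow 3, any HFD array or HFD+APS 3 (up to 0.0927). Cyp7a1 stood at 0.73 ± 0.54 (adjusted p = 0.511; -0.15 within the slide). NRF2 antioxidant genes (18 measured, 0 past and 0 adjusted over the list alone) had a median of -0.24 (adjusted p = 0.00908; adjusted p = 0.33 with an estimated correlation; -0.14 within the slide, 0.083). Nqo1, a quinone reductase, stood at -0.67 ± 0.16 (adjusted p = 0.0888).

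Male-biased genes (16 measured) had 2 higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.56 (adjusted p = 7.96e-05, and 0.33 with an estimated correlation), and 0.55 within the slide. The called genes were Cyp7b1 (1.40 ± 0.22, its call lost as above) and Susd4 (1.31 ± 0.18, adjusted p = 0.0191; 1.39 within the slide, 0.0648), the latter call lost without HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.0698). Hsd3b5, a steroid reductase of male liver, stood at 4.04 ± 0.80 (adjusted p = 0.0538). In the female-biased list (16 measured) 1 rose and 3 fell (3 and 5 adjusted over the list alone). The median was 0.08, the mean -0.25 and the test pointed down (adjusted p = 0.535; 0.16 within the slide). Cyp2b9 fell by 2.52 ± 0.26 (adjusted p = 0.00908; -2.83 within the slide, 0.0193). Cyp2b13 fell by 2.47 ± 0.32 (adjusted p = 0.0176; -2.85 within the slide, 0.0387), a call lost without HFD 1, HFD+APS 2 or HFD+APS 3 (up to 0.0595). Hao2 fell at least 4.23-fold (adjusted p = 0.0226), a call lost without HFD 1, HFD 2 or HFD+APS 3 (up to 0.0651). Cyp3a16 (2.12 ± 0.36) and Cyp3a11 (2.28 ± 0.41) rose and lost their calls without any chow array, HFD 2, HFD+APS 2 or HFD+APS 3 (adjusted p up to 0.117 and 0.129), Cyp3a11 also without HFD 1. The P450 list as a whole (31 measured, 2 higher and 2 lower, 6 and 4 adjusted over the list alone) had a median of 0.11 (adjusted p = 0.221; 0.23 within the slide). It was called without HFD 2 (0.32, adjusted p = 0.00865), after normexp (0.16, 0.045) and without a filter on dim probes (0.11, 0.0177).

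Of 19 cell cycle genes 0 rose and 9 fell (0 and 12 adjusted over the list alone). The median was -1.19 (adjusted p = 1.12e-10, and 0.33 with an estimated correlation), and -1.19 within the slide. Ccnb2 fell by 2.10 ± 0.21 (adjusted p = 0.00908; -2.17 within the slide, 0.0318) and Ccne1, the cyclin of the G1 to S transition, by 1.75 ± 0.18 (adjusted p = 0.01; -1.91 within the slide, 0.0278). Cdc20 fell by 2.46 ± 0.33 (adjusted p = 0.0181; -2.28 within the slide, 0.0828), a call lost without HFD+APS 2 or HFD+APS 3 (up to 0.0625). Mki67 fell by 1.66 ± 0.27 (adjusted p = 0.0311; -1.28 within the slide, 0.157), a call lost without any chow array, HFD 2, HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.0909). Outside the list, Cdkn3, a phosphatase that acts on cyclin-dependent kinases, fell 7.97-fold (-2.99 ± 0.33, adjusted p = 0.0109; -2.73 within the slide, 0.0512).

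Several immune and stromal lists were called lower over all arrays and lost that call within the slide. The inflammatory list (19 measured, 0 past, 0 and 3 adjusted over the list alone) had a median of -0.75 (adjusted p = 0.00037; adjusted p = 0.605 with an estimated correlation). Within the slide it was -0.17 (adjusted p = 0.473, and 0.406 with the fixed block), and Ccl2 stood at -1.78 ± 0.55 (adjusted p = 0.152). Acute phase proteins (25 measured, 0 past and 0 adjusted over the list alone) had a median of -0.71 (adjusted p = 0.0238; adjusted p = 0.937 with an estimated correlation). Within the slide it was 0.15 (adjusted p = 0.718, and 0.732 with the fixed block). Interferon genes (25 measured) stood at -0.27 (adjusted p = 0.00871; adjusted p = 0.883 with an estimated correlation), and -0.02 within the slide (0.889). Monocyte-derived macrophage markers (11 measured) stood at -0.70 (adjusted p = 0.00397; adjusted p = 0.605 with an estimated correlation), and -0.32 within the slide (0.569). Neutrophil markers (5 measured) stood at -1.09 (adjusted p = 0.0354; adjusted p = 0.605 with an estimated correlation), and -0.45 within the slide (0.473). In these 3 lists 0 genes passed and 0 did adjusted over the list alone. Immediate early and heat shock genes (18 measured, 0 past, 1 and 2 adjusted over the list alone) stood at -0.37 (adjusted p = 0.0356; adjusted p = 0.605 with an estimated correlation), and -0.03 within the slide (0.653). Stellate and fibrosis markers (18 measured, 0 past, 0 and 2 adjusted over the list alone) stood at -0.16 (adjusted p = 0.0401; adjusted p = 0.937 with an estimated correlation), and -0.14 within the slide (0.433). Col1a1 stood at -1.69 ± 0.45 (adjusted p = 0.112). Without HFD 3 the calls were lost for acute phase (-0.11, adjusted p = 0.978), interferon (-0.16, 0.474), immediate early (-0.19, 0.525), monocyte-derived (-0.34, 0.0935), neutrophil (-0.39, 0.453) and stellate lists (-0.12, 0.328). Leaving out HFD+APS 2 or HFD+APS 3 ended the acute phase (0.164 and 0.121), immediate early (0.136 and 0.117) and neutrophil calls (0.0651 and 0.117). The interferon call was lost without HFD+APS 2 (0.23) and the stellate call without HFD+APS 1 or HFD+APS 3 (0.0535 and 0.117).

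Kupffer cell markers (15 measured) had a median of -0.17 (adjusted p = 0.535) and 0.28 within the slide (adjusted p = 0.217, and 0.0402 with the fixed block). The clock list (17 measured) had a median of -0.24 (adjusted p = 0.775) and -0.63 within the slide. HFD+APS 1 stood apart, with a clock score of -0.65 against 0.29 and 0.09 in the other HFD+APS arrays. The hepatocyte list (14 measured, 1 higher and 0 lower, 3 and 1 adjusted over the list alone) had a median of 0.01 (adjusted p = 0.535; 0.16 within the slide). Its called gene Cps1, the first enzyme of the urea cycle, rose by 1.11 ± 0.19 (adjusted p = 0.0347; 1.20 within the slide, 0.102), a call lost without chow 1, chow 3, HFD 1, HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.106). The unfolded protein response list had a median of -0.26 (adjusted p = 0.103; -0.07 within the slide). It was called without chow 1 (-0.26, adjusted p = 0.0326), HFD 1 (-0.37, 0.00912) or HFD 2 (-0.36, 0.0347). Medians were 0.04 for glucose metabolism (adjusted p = 0.756; 0.03 within the slide) and for oxidative phosphorylation (adjusted p = 0.535; -0.01 within the slide; 0.13 and 0.0447 without HFD 1). They were -0.06 for lymphocytes (adjusted p = 0.806; 0.41 within the slide) and -0.50 for exocrine pancreas (adjusted p = 0.073; -0.12 within the slide). Median, mean and test differed in sign for endothelial (0.02, -0.01 and up, adjusted p = 0.806; 0.17 within the slide), cholangiocyte (0.10, 0.00 and down, adjusted p = 0.924; 0.23 within the slide) and red blood cell markers (0.01, -0.05 and down, adjusted p = 0.924; 0.77 within the slide). Apart from Cps1, 0 genes of these lists passed, and adjusted over the list alone 1 glucose gene was higher and 1 pancreas gene was higher and 2 lower.

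Among the largest single changes, Srgap3, which regulates Rac, rose at least 4.02-fold (adjusted p = 0.00372, and 0.0164 within the slide; chromosome 6, 112668239 to 112668298). Adgrf1, an adhesion receptor, rose at least 3.9-fold (adjusted p = 0.000609, and 0.00665 within the slide). Lgals1 fell by 3.35 ± 0.20 (adjusted p = 0.000609; -3.67 within the slide, 0.00665, and 0.0457 with the fixed block). Lockd fell by 3.50 ± 0.33 (adjusted p = 0.0072; -3.46 within the slide, 0.0314) and Slc22a29, an organic anion transporter, by 2.97 ± 0.21 (adjusted p = 0.00152; -3.31 within the slide, 0.00665). Vmn1r79, a vomeronasal receptor, passed (adjusted p = 0.01) with too little signal for a fold. Eif4ebp3 rose by 2.22 ± 0.27 and lost its call without HFD+APS 2 (adjusted p = 0.0562). Meg3 rose by 2.51 ± 0.41 to 0.06 ± 0.57 (2.91 within the slide, 0.0713) and Atp12a by 2.15 ± 0.34 (2.27 within the slide). Their calls were lost without chow 3, HFD 1, HFD+APS 2 or HFD+APS 3 (up to 0.101 and 0.0974), Meg3 also without chow 2 or HFD 2 and Atp12a without HFD 3. Fam183b fell at least 4.74-fold, a call lost without HFD 1, HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.0714), and Mmd2 fell by 3.08 ± 0.53, a call lost without any array but HFD+APS 1 (up to 0.0979).

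In total 84 features were higher and 181 lower in HFD+APS than in HFD (1.5% of 17637; 3150 at an unadjusted p under 0.05). Within the shared slide 199 passed, 120 higher and 79 lower, 74 of them among the 265. With slide as a fixed block, which rests on the same 4 arrays, 15 passed, 8 higher and 7 lower, 7 of them among the 265. Within the slide 17 of 29 called genes named by rule kept their call. Called groups did not overlap, so signs had to hold. With the fixed block 2 kept it (Lgals1 and Mogat1), and 13 in all 9 fits leaving out 1 array. Of 14 called lists, 13 kept their sign and 5 their call within the slide. With a random slide block 10 kept their call, all but acute phase, immediate early, stellate (adjusted p = 0.06 each) and neutrophil (0.0571). The count was 578 without HFD+APS 1 (no shared slide), 155 without chow 1 or 2 and 137 without HFD 2. It was 105 without chow 3, 99 without HFD 3, 92 without HFD 1 and 51 without HFD+APS 2 or 3.

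The comparison of HFD+APS with chow asked which differences from the control diet were present with the fat diet and APS together. Cyp2b9, Cyp2b13 and Sult3a1 were above chow, the heat shock genes Hspa1a and Hspa1b were lower, and 20 of 21 fat storage and 18 of 19 cell cycle genes did not pass. Cyp2b9 was 2.0 ± 0.26 above chow on the log2 scale (adjusted p = 0.0138), at 3.66 ± 0.27 against 1.66 ± 0.17 (mean ± SD, n = 3 per group), and Sult3a1 was 1.21 ± 0.17 above (adjusted p = 0.0173). Hspa1a fell by 3.14 ± 0.34 (adjusted p = 0.0109; chromosome 17, 35106766 to 35106825) and its paralog Hspa1b by 2.83 ± 0.34 (adjusted p = 0.0125), near-identical genes whose separate values are uncertain. Without chow 2 or chow 3 each of these 4 calls was lost (adjusted p up to 0.0621 for Cyp2b9, Hspa1a and Hspa1b and 0.0861 for Sult3a1). The calls of Cyp2b9 and Sult3a1 were also lost without HFD+APS 2 or HFD+APS 3 and that of Hspa1b without HFD+APS 2.

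Of 21 fat storage genes 0 rose and 1 fell (1 and 1 adjusted over the list alone). Median and mean were -0.02 and -0.03 while the test pointed up (adjusted p = 0.447). Plin4 fell by 1.61 ± 0.33 (adjusted p = 0.0428), a call lost without any chow array, HFD 3, HFD+APS 2 or HFD+APS 3 (up to 0.138). Cidea (1.19 ± 0.65, adjusted p = 0.296), Mogat1 (0.51 ± 0.13, adjusted p = 0.0659), Cd36 (0.33 ± 0.19, adjusted p = 0.315), Cidec (-0.57, adjusted p = 0.67) and Pparg (-0.19, adjusted p = 0.708) did not pass. Lipogenesis genes (20 measured, 0 higher and 1 lower, 1 and 4 adjusted over the list alone) had a median of -0.38 (adjusted p = 0.299). Gpam fell by 0.70 ± 0.12 (adjusted p = 0.0306), and Scd1 (-0.37, adjusted p = 0.734), Fasn (-0.67, adjusted p = 0.266) and Srebf1 (0.06, adjusted p = 0.946) did not pass. Among 23 cholesterol genes Hsd17b7 alone fell, by 0.66 ± 0.14 (adjusted p = 0.0471; 0 and 1 adjusted over the list alone). The list median was -0.25 (adjusted p = 0.166), with Sqle at -1.02 (adjusted p = 0.458). The cholesterol list was called without chow 2 (-0.54, adjusted p = 0.000267), HFD+APS 2 (-0.43, 0.00609) or HFD+APS 3 (-0.34, 0.0286). Gpam lost its call without any chow array, HFD 2, HFD+APS 2 or HFD+APS 3 (up to 0.103) and Hsd17b7 without any array but HFD+APS 1 (up to 0.138). In the bile acid list (26 measured, 0 past and 0 adjusted over the list alone) the median was 0.21 (adjusted p = 0.00511; adjusted p = 0.996 with an estimated correlation), with 22 of 26 log2 changes positive. Cyp7a1 stood at 0.59 (adjusted p = 0.534). Scarb1, the HDL receptor, rose by 0.65 ± 0.14 (adjusted p = 0.0429) as the called gene of 19 in the lipoprotein list (2 and 0 adjusted over the list alone; median 0.15, adjusted p = 0.299). Its call was lost when any 1 of the 9 arrays was left out (up to 0.124). Pfkfb1, a regulator of glycolysis, rose by 0.87 ± 0.18 (adjusted p = 0.0419), the called gene of 18 in the glucose list (1 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.996). Its call was lost without any chow array, HFD 1, HFD 2, HFD+APS 2 or HFD+APS 3 (up to 0.135). Fatty acid oxidation genes had a median of -0.07 (adjusted p = 0.447; 0 and 0 adjusted over the list alone), with Fgf21 at -1.05 (adjusted p = 0.257) and Cyp4a14 at -0.38 (adjusted p = 0.41).

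The female-biased list (16 measured) had 3 higher and 0 lower (3 and 0 adjusted over the list alone), Cyp2b9, Sult3a1 and Cyp2b13, with a median of 0.16 (adjusted p = 0.141; 0.05 and 0.0277 without HFD+APS 3). Cyp2b13 rose by 1.93 ± 0.32 (adjusted p = 0.0275). Its call was lost without any chow array, HFD+APS 2 or HFD+APS 3 (up to 0.105). The P450 list (31 measured) had 2 higher, Cyp2b9 and Cyp2b13, and 0 lower (2 and 0 adjusted over the list alone; median 0.02, adjusted p = 0.399). The male-biased list had 0 past (0 and 0 adjusted over the list alone; median 0.09, adjusted p = 0.996). Immediate early and heat shock genes (18 measured, 0 higher and 3 lower, 1 and 6 adjusted over the list alone) had a median of -0.53 (adjusted p = 0.00521; adjusted p = 0.996 with an estimated correlation). Beside the Hspa1 paralogs, Gadd45b fell by 1.63 ± 0.34 (adjusted p = 0.0465), a call lost without any array but HFD+APS 1 (up to 0.145). The cell cycle list (19 measured) had 0 higher and 1 lower (0 and 1 adjusted over the list alone), with a median of 0.05 (adjusted p = 0.62). Ccne1 fell by 0.90 ± 0.18 (adjusted p = 0.042), a call lost without any chow array, HFD 1, HFD 2, HFD+APS 1 or HFD+APS 2 (up to 0.128).

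Interferon genes (25 measured) had 2 higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.54 (adjusted p = 2.79e-06; adjusted p = 0.996 with an estimated correlation). Psmb9 rose by 0.91 ± 0.17 (adjusted p = 0.0345) and Ifit3 by 0.83 ± 0.16 (adjusted p = 0.0395), calls lost without any chow array, HFD 2, HFD+APS 2 or HFD+APS 3 (up to 0.125 and 0.133), Ifit3 also without HFD 1. Kupffer cell markers (15 measured, 0 past and 0 adjusted over the list alone) had a median of 0.88 (adjusted p = 0.000483; adjusted p = 0.996 with an estimated correlation). Without chow 2, whose score of -1.32 was the lowest, the median was 0.48 and the list stayed called. Clec4f stood at 1.02 ± 0.28 (adjusted p = 0.0771). Endothelial markers (13 measured, 1 higher and 0 lower, 6 and 0 adjusted over the list alone) had a median of 0.44 (adjusted p = 0.000418; adjusted p = 0.996 with an estimated correlation). Fcgr2b, an inhibitory Fc receptor, rose by 1.14 ± 0.25 (adjusted p = 0.049), a call lost without any array but chow 1 (up to 0.143). Stellate markers (18 measured, 0 past and 0 adjusted over the list alone) had a median of 0.38 (adjusted p = 0.0136; adjusted p = 0.996 with an estimated correlation). They lost their call without chow 2 (0.12, adjusted p = 0.238) or HFD+APS 1 (0.24, 0.0963), with Col1a1 at 0.39 (adjusted p = 0.631). The exocrine pancreas list (5 measured, 0 higher and 2 lower, 0 and 4 adjusted over the list alone) had a median of -0.90 (adjusted p = 0.0259; adjusted p = 0.934 with an estimated correlation). It lost its call without chow 1 (-0.89, 0.0687), after normexp (-0.25, 0.133), without a filter on dim probes (-0.86, 0.149) and with probes well above background on all 9 arrays (-0.66, 0.249). Its called genes Cel, a bile salt-stimulated lipase (-0.66 ± 0.13, adjusted p = 0.0399), and Ctrl, a chymotrypsin-like protease (-1.19 ± 0.24, adjusted p = 0.0412), lost their calls without any chow array, HFD 2, HFD+APS 2 or HFD+APS 3 (up to 0.131 and 0.141). Ctrl also lost it without HFD 1.

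In the remaining lists 0 genes passed over all genes. Medians were -0.28 for inflammatory genes (adjusted p = 0.447, Ccl2 at 0.09), 0.11 for acute phase proteins (adjusted p = 0.437) and 0.15 for monocyte-derived macrophages (adjusted p = 0.263; 0.25 and 0.0314 without HFD+APS 2). For neutrophils the median was 0.25 (adjusted p = 0.996) and for lymphocytes -0.25 (adjusted p = 0.263; -0.56 and 0.0414 without HFD+APS 1). Medians were -0.19 for NRF2 genes (adjusted p = 0.263), 0.11 for the clock (adjusted p = 0.436; 0.27 and 0.0414 without HFD+APS 1), 0.01 for oxidative phosphorylation (adjusted p = 0.594), -0.16 for cholangiocytes (adjusted p = 0.996) and 0.18 for adipocytes (adjusted p = 0.447). Signs differed between median, mean and test for the unfolded protein response (-0.10, 0.00 and up, adjusted p = 0.665), hepatocytes (-0.01, -0.02 and up, adjusted p = 0.996) and red blood cells (-0.01, -0.02 and up, adjusted p = 0.996). Adjusted over the list alone, 2 monocyte-derived markers were higher and 1 lower, 1 NRF2 gene was lower, and 0 passed in the others.

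Of the largest single changes, the same immunoglobulin kappa variable gene fell at least 2.74-fold (adjusted p = 0.00457) and Btbd35f1 at least 3.6-fold (adjusted p = 0.00367). Tmem59l fell at least 5.48-fold (adjusted p = 0.00416) and Pex5l, a subunit of neuronal ion channels, at least 2.04-fold (adjusted p = 0.00457). These 4 calls held in all 9 fits that left out 1 array. Gpr85 (at least 2.5-fold) and Krtap3-2 (at least 2.79-fold) fell, and Wif1, a Wnt inhibitor, rose at least 2.18-fold. Their calls were lost without chow 2 or chow 3 (up to 0.0621, 0.0991 and 0.101), Wif1 and Krtap3-2 also without HFD+APS 2 or HFD+APS 3 and Krtap3-2 without chow 1. Gpcpd1 rose by 1.80 ± 0.30, Ncmap by 1.64 ± 0.24, Fabp7 by 1.70 ± 0.35 and Cav1, the caveolae protein, by 1.99 ± 0.40 with probes from 0.39 to 1.99. These 4 lost their calls without chow 2, chow 3, HFD+APS 2 or HFD+APS 3 (up to 0.0991, 0.0654, 0.125 and 0.141), all but Ncmap also without HFD 2, and Fabp7 without chow 1, HFD 1 or HFD 3. Over all features 169 were higher and 443 lower (3.5% of 17637; 4438 at an unadjusted p under 0.05). Higher features made up 27.6% of the calls, and 41.7% of 631 calls after normexp background correction. The dimmest of 5 brightness classes held 10 higher and 142 lower (median -0.239) and the brightest 37 and 33 (0.036). The count was 21 without chow 3, 23 without chow 2, 46 without HFD+APS 2, 73 without HFD+APS 3, 223 without HFD 2, 232 without chow 1 and 1609 without HFD+APS 1. With slide as a random block 165 features passed and 11 of the 29 called genes named by rule kept their call. Of the 29, 4 held in all 9 fits that left out 1 array, and the chow slide held no other group.

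The overlap of the comparisons asked which changes under the fat diet were smaller with APS. Of the 1929 features past the threshold in HFD against chow, 86.4% had the opposite sign in HFD+APS against HFD (92.5% of those higher and 82.1% of those lower in HFD). Because both comparisons use the same HFD arrays, simulated data with the HFD changes and no APS effect gave 62.4% (59.3 to 65.4% over 100 simulations). Features past both thresholds in opposite directions numbered 179, 114 up with HFD and down with HFD+APS and 65 the reverse, against 8.2 and 5.4 for independent lists, and 7 moved the same way (1 up and 6 down against 3.8 and 11.6). Independent lists leave out the shared arrays. With the same shared arrays and no APS effect, simulations gave 0.03 features past both thresholds in opposite directions (0 to 1). These values argue against sharing alone as the source of the 179 features. No simulation held an APS effect unrelated to the HFD changes, so a part from sharing stays possible. The changes correlated at -0.588 across features, which are not independent replicates, with a covariance of -0.150. Simulations with no effect gave -0.499 (-0.551 to -0.468) and -0.0349. Simulated features are independent, so ranges may be too narrow. HFD+APS 1, on the slide of the HFD arrays, gave 86.5%, HFD+APS 2 79.3% and HFD+APS 3 83.6%. The median share of the HFD change that was taken back was 0.42, against 0.0631 (0.0419 to 0.0795) in simulations with no APS effect. The 8 genes with the largest product of fitted opposite changes were Cidea, Lockd, Fam183b, Cyp2b9, Cyp2b13, Adgrv1 and Lgals1, up with HFD and down with HFD+APS, and Srgap3 in the other direction. The rank of Lockd, Fam183b and Srgap3 is uncertain, since a group was not well above background. Adgrv1 fell by 2.6 ± 0.41 in HFD+APS against HFD (adjusted p = 0.0294; -3.47 within the slide, 0.0164), a call lost without any chow array, HFD 1, HFD 2, HFD+APS 2 or HFD+APS 3 (up to 0.0733).

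**Figure D3:**
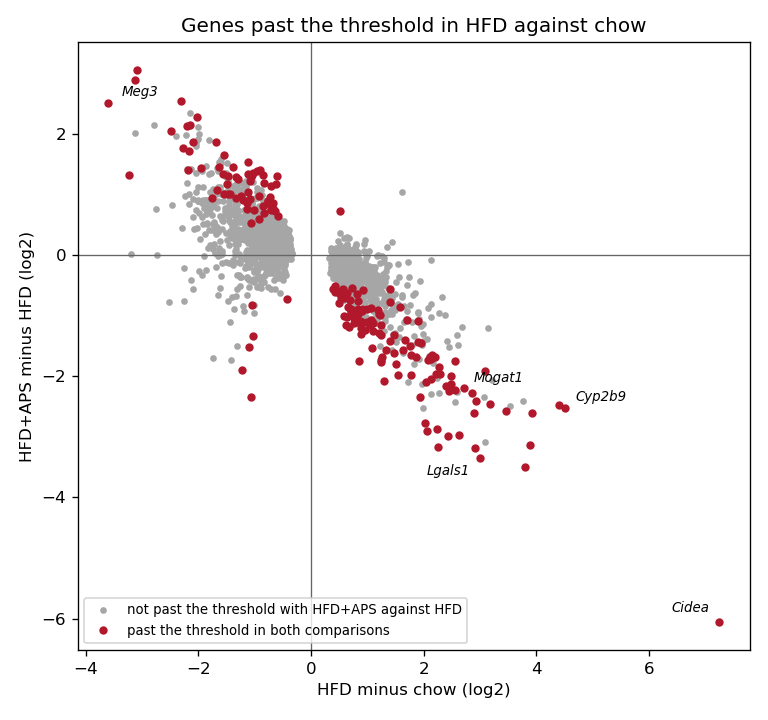
Each point is 1 of the 1929 features past the threshold in HFD against chow, with its log2 change in that comparison on the horizontal axis and its log2 change in HFD+APS against HFD on the vertical axis. Red points passed in both comparisons, 179 of them with changes of opposite signs, at the upper left and lower right, and 7 with changes of 1 sign.

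Against chow, HFD and HFD+APS shared 345 features past both thresholds in the same direction and 3 in opposite directions. Of the 345, 241 were down, against 28.3 for independent lists, and the rest up, against 7.7. Simulations gave 948 such features (888 to 1020) with the HFD changes and no APS effect, and 0.01 with no effect. The changes of all features correlated at 0.600, against 0.501 (0.470 to 0.532) in simulations with no effect and 0.827 (0.816 to 0.838) with the HFD changes and no APS effect, with a covariance of 0.155 against 0.035 in simulations with no effect (difference 0.12). The 3 shared chow arrays may account for part of the excess over independent lists. Of the 179 features turned back, 166 did not pass in HFD+APS against chow, which does not show that they equalled chow.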

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

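The restriction to matched features and the common floor were chosen after seeing the data; the other alternatives were planned. Values of HFD against chow, HFD+APS against HFD and HFD+APS against chow are given in that order, with 1929, 265 and 612 features past the threshold in the reported fit, and after them the share of HFD changes with the opposite sign in HFD+APS (86.4%). Normexp, quantile normalization, median scaling, the authors' table, probes well above background on all 9 arrays, the mean over probes, the trend with a robust prior and both added alternatives gave 1494 to 2269, 224 to 355, and 525 to 884 features and 84.1 to 87.1%, within 1.5 times each count, but with changed membership. With the common floor 1468, 152 and 460 of the reported calls were kept, while 5.5, 7.2 and 6.9% lost their sign. After normexp 1199, 154 and 353 were kept. Higher features made up 27.6% of calls in HFD+APS against chow and 41.7% after normexp. A fold change of at least 2, which is stricter by construction, left 668, 164 and 288. Without a filter on dim probes 798, 79 and 224 passed among more features, slide as a random block gave 684, 164 and 165, and array weights gave 3072, 1269 and 3184 with a share of 79%; the cause was not tested. With only the groups compared 25 passed in HFD+APS against HFD and 347 in HFD+APS against chow, with fewer arrays for the spread, and the share was 82.4%. A fixed slide block left 15 features in HFD+APS against HFD, and 199 passed within that slide. The difference is the same, so only its fitted spread differs. Over all features, called or not, the share with opposite signs was 67.4%, against 66.7% (65.9 to 67.5%) in simulations with no effect and 62.6% (61.7 to 63.7%) with the HFD changes and no APS effect.

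Leaving out each array in turn gave 365 to 2712 features in HFD against chow, 51 to 578 in HFD+APS against HFD, 21 to 1609 in HFD+APS against chow and a share of 74.8 to 92.6%, with a lone pair of arrays in the reduced group. In that order, the lowest came without chow 2, HFD+APS 2 or 3, chow 3 and HFD+APS 1. The highest counts came without HFD+APS 1, the highest share without chow 2. The 578 and 74.8% compare HFD+APS with HFD across slides only. Leaving out any array moved at least 1 count by over 1.5 times. The cause was not tested.

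Equal replicate numbers did not mark pairs: deviations from the group mean correlated at -0.175 to 0.164 between same-numbered arrays of different groups, and 4 of 9 arrays deviated most like their own number. A block for replicate number gave 1324, 82 and 296 features and 85.6%, and its cause was not tested beyond this check of the pairing.

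The added alternatives were run for the counts and the share only. Of 2037 values for list results under the others, 1900 kept direction and side of the threshold, 95 lost a call, 38 gained one and 4 reversed; of 8883 values for named genes, 7967, 634, 281 and 1 did. Socs3 reversed to 0.30 in HFD against chow (adjusted p = 0.727) with the mean over its probes, which differ in sign. Oxidative phosphorylation (-0.02 in HFD against chow) ranged from -0.09 without HFD 1 to 0.10 without HFD 3, where it was called in the other direction (adjusted p = 0.0339). In HFD+APS against HFD, acute phase proteins reversed to 0.15 with the fixed slide block (adjusted p = 0.732) and within the slide (0.718), and Kupffer cell markers to 0.28 with the fixed block (0.0402). List calls also ended without the filter on dim probes for acute phase in HFD against chow (0.0613) and for acute phase (0.242), immediate early (0.242), stellate (0.224), NRF2 and interferon lists (both 0.15) in HFD+APS against HFD. Array weights ended those of acute phase in HFD against chow (0.108) and stellate in HFD+APS against HFD (0.0713), as the mean over probes did for the latter (0.0603), and probes on all 9 arrays that of stellate in HFD+APS against chow (0.101). Calls were gained after normexp by immediate early genes in HFD against chow (0.0419) and cholesterol genes in HFD+APS against chow (0.0476), and under other single alternatives by unfolded protein response, pancreas and female-biased lists (0.0316 to 0.0489). The cause was not tested for these lists. Signal over background limits what can be read from dim features: 353, 52 and 78 of the features past the threshold had a group not well above background, and their folds are bounds.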

Other observations

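The tests for DNA or unspliced RNA, for resident and monocyte-derived macrophages and for the filter on dim probes, and the shrinkage in the simulations, were chosen after the result was seen. Gene groups also picked after seeing the values (urea cycle, sulfur amino acid enzymes, p53 targets, and galectins, annexins and S100 proteins) were looked at without an enrichment test, and they are not reported here as groups.

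Splitting the 6 arrays of a comparison into 3 and 3 gives 10 splits, which are too few for a share under 0.05. The real split, 1 of the 10, gave 1929 features in HFD against chow, 265 in HFD+APS against HFD and 612 in HFD+APS against chow, and the highest of the other splits gave 0, 2 and 0.

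Of 1929 features called in HFD against chow, 86.4% had the opposite sign in HFD+APS against HFD, against 62.4% in simulations with no APS effect. The shared HFD arrays are argued against as the whole cause. For this test each HFD array was left out of the calls and then used alone against the HFD+APS arrays, and 75.2% of the features so called had the opposite sign on average (64.0, 83.0 and 78.7% for HFD 1, HFD 2 and HFD 3). With the HFD+APS array of the same slide the average was 75.5% (64.5, 81.6 and 80.3%), which rests on 1 array, so an effect of the slides may contribute and stays open. Whether APS weakened the liver's response to the fat diet was not tested, and this design cannot separate it from the choice of livers by their fat content.

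In the cell cycle list 12 of 19 genes rose in HFD against chow and 9 fell in HFD+APS against HFD, and the list calls were lost with an estimated correlation (adjusted p = 0.459 and 0.33). A single HFD mouse as the source is argued against, since the lowest HFD score (0.60) exceeded the highest other score (-0.08) by 0.68, with a largest SD within a group of 0.29. A larger share of macrophages in HFD stays open, as their markers need not move as far as cell cycle genes. With APS the cell cycle median was -1.19. It was -0.17 for resident macrophage markers (SD over markers 0.19) and -0.70 for monocyte-derived ones (SD 0.38). For the rise in HFD the marker medians (1.05 and 1.04) lay within the SD over markers (0.52 and 0.81) of the cell cycle median, 1.07. Hepatocytes, other dividing cells and the diet itself stay open as sources and were not tested.

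In the 3528 dimmest features the medians against chow were -0.193 in HFD and -0.239 in HFD+APS. The filter on dim probes, which the chow arrays alone can pass, may contribute: with probes well above background on at least 3 arrays outside chow, a filter chosen after seeing the data that favours the other groups, they were -0.043 and -0.12, and with no filter 0.682 and 0.016. The higher background of the slide with the HFD arrays stays open. The HFD+APS arrays on the other slide also lay below chow, the higher at -0.227 (SD of the chow arrays 0.088), but chow alone can pass the reported filter. The value depends on the filter: -0.28 with none, -0.144 with that outside chow, and -0.093 with probes on all 9 arrays (medians -0.072 in HFD and -0.092 in HFD+APS). DNA or unspliced RNA in the chow samples may contribute: 197 receptor and keratin-associated genes, most of them silent in liver, had medians of -0.49 in HFD and -0.68 in HFD+APS against chow, with 40 and 28 lower and 0 higher past the threshold (-0.48 and -0.60 for the 64 well above background on all 9 arrays, 0.46 and -0.07 for 1101 with no filter). Causes that lower dim features stay open, but these genes had lower medians than those with each filter, and the labels state a DNase step. The chow slide held no other group, so handling or slide cannot be told apart from diet.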
